A study of Homo sapiens with 6 samples.

How the data were processed

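Total RNA of BCWM1, an established human cell line of Waldenström macroglobulinemia (a lymphoma of B cells and plasma cells), was measured on 6 microarrays. Per the labels, RNA was isolated with a column kit and copied into biotin-labelled cRNA by in vitro transcription. The samples form 2 groups of 3, parental cells and mutated cells, taken from the sample titles. Replicates are numbered 1 to 3 in both groups. How the mutated cells were made, and whether a vector control was kept, is not given in the sources used here. The labels do not say that the samples of a group are separate cultures, so p-values measure only the spread between these samples, which may be technical.

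The deposited values are the authors' intensity per probe set on a linear scale. The summary method, background correction and normalization between arrays are not given in the sources used here. No detection calls were used here. The table holds 54613 probe sets and no value column belongs to a sample outside the 6. The platform annotation gives 1 gene symbol for 41091 probe sets, several for 1801 and none for 11721. Of the probe sets with 1 symbol, 41037 were matched by Entrez ID to a RefSeq gene table of assembly GRCh38.p14, and 0 symbols changed. That table was used only for names and for the order of neighbouring genes.

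Median intensity was 29.13, 28.46 and 28.99 on the parental arrays and 31.42, 30.93 and 31.83 on the mutated arrays. Between 2.01% and 2.36% of the values of an array were exactly 1. The 6 arrays limit the precision, which is lowest for dim probe sets. The median SD of the log2 values of tested probe sets in the top quartile of brightness was 0.044 in parental and 0.045 in mutated cells, against 0.13 and 0.16 in the bottom quartile.

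Values were transformed as log2(intensity + 16). The pseudocount of 16 understates the fold change of dim genes, and every fold change given is on that scale. The 40% of probe sets with the lowest mean log2 value over all 6 samples were left out. The remaining 32768 were fitted with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with group as the only term, and p-values were adjusted by the Benjamini-Hochberg method over all of them, with a threshold of 0.05. A gene was represented by its tested probe set with the highest mean, among probe sets with 1 symbol. Probe sets of several symbols were not named. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over 40 lists, all with at least 5 tested genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

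The groups, the model, the lists, the alternatives and the rule for named genes were fixed before the data were examined, apart from those named as later choices. The rule took every CXCR4 probe set. It took the 14 genes with the largest rise and the 14 with the largest fall among those past the threshold whose 3 mutated values all lay on one side of the 3 parental values. Sex-linked RNA markers, unnamed loci and antigen receptor segments were left out. It also took up to 4 members of each list past camera and up to 2 members past the threshold of each other list, those with the smallest adjusted p. Where 5 or fewer members of a list moved one way, genes outside the rule are named as well, and these were chosen after their values were seen.

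The alternatives were quantile normalization, median centring of each array, no filter on dim probe sets, a filter on the dimmest 60%, eBayes with its trend and robust options, array weights, pseudocounts of 1 and 64, and the replicate number as a block. Others were the mean over a gene's probe sets, only probe sets without the suffixes _s_at and _x_at (which mark probes shared by several transcripts), each sample left out in turn, a correlation estimated for each list, and the set test fry.

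The procedure was tested on simulated data for the mutated against parental comparison, with 200 of 32768 probe sets shifted. It recovered 43% of those shifted by a log2 value of 0.5 and 77% of those shifted by 1, and called 8 unchanged probe sets. With no probe set shifted it called 0. In 20 simulations with no list shifted, camera called 0 of the 40 lists. With 1 list shifted it called 2. The simulated noise was independent between probe sets, so these runs do not show how often camera errs on correlated genes. On the real arrays, other groupings of the 6 samples gave up to 7 lists. Those groupings mix the groups unequally, so part of the group difference remains in them. Their list counts therefore do not show how often camera errs either. The simulated share of changed probe sets was also far smaller than in the real comparison, where 15553 were called, so recovery there may differ.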

Results

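Gene expression was compared between parental BCWM1 cells and BCWM1 cells labelled as mutated, with 3 samples in each group. The series title ties the mutation to CXCR4, the receptor of the chemokine CXCL12, and writes it as C1013G. The title gives no numbering for that position, and changes in this gene are usually numbered along its coding sequence. The comparison asks which mRNA levels differ between the mutated cells and the parental cells they are set against. The 6 arrays each gave 54613 probe set intensities, with medians from 28.46 to 31.83. Over the tested probe sets, Pearson's r across probe sets was 0.994 to 0.996 within a group and 0.967 to 0.970 between groups. Probe sets are not independent replicates.

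CXCR4 mRNA was abundant in both groups and lower in mutated cells on its 3 probe sets. The probe set with the suffix _s_at fell from 1987 ± 150 to 1333 ± 100 (SD, n = 3), a log2 change of −0.57 (SE 0.081; limma with Benjamini-Hochberg adjustment, adjusted p = 0.0016). The probe set with the suffix _x_at fell from 1971 ± 161 to 1391 ± 63.6 (SD, n = 3), a log2 change of −0.50 (SE 0.074; limma with Benjamini-Hochberg adjustment, adjusted p = 0.0020). The brightest probe set, with the plain suffix _at, represented the gene and fell from 4741 ± 52.1 to 4259 ± 85.5 (SD, n = 3), a log2 change of −0.15 (SE 0.045; limma with Benjamini-Hochberg adjustment, adjusted p = 0.030). On each probe set the 3 mutated values lay below the 3 parental values. The call on this brightest probe set was lost without the filter on dim probe sets (limma, adjusted p = 0.068), with the replicate number as a block (0.070), and when any of the 6 samples was left out (0.051 to 0.089). The probe sets do not tell the mutated from the normal transcript in these data, and where they lie relative to the mutated site was not analysed here.

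**Figure D1:**
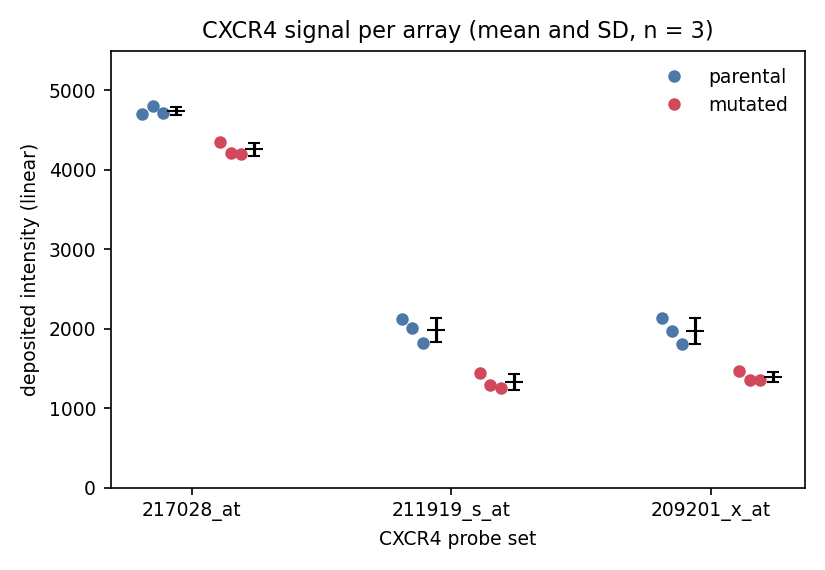
Deposited linear intensity (y axis) of the 3 CXCR4 probe sets (x axis) on each array. Points are arrays, blue for parental and red for mutated cells, and black bars are the mean and SD (n = 3). The mutated arrays lie below the parental arrays on every probe set, with a log2 change of −0.15 on the brightest probe set, −0.57 on _s_at and −0.50 on _x_at.

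On the log2(intensity + 16) scale, on which the genes are ranked, the largest rise was in PLS3, which encodes the actin-bundling protein plastin 3, from an intensity of 15.3 ± 2.36 in parental to 1909 ± 55.8 in mutated cells (SD, n = 3), a log2 change of 5.94. WNT5A, a secreted Wnt ligand, rose from 19.0 ± 3.59 to 923 ± 32.9 (SD, n = 3). FABP4, a fatty acid carrier, rose from 5.88 ± 0.961 to 670 ± 29.5 (SD, n = 3), and GPAT3, an enzyme of glycerolipid synthesis, from 6.39 ± 1.47 to 945 ± 39.6. On that scale the largest fall was in CD93, a surface glycoprotein, from 785 ± 10.03 to 11.5 ± 3.50 (SD, n = 3), a log2 change of −4.87. IFI27, an interferon-induced gene, fell from 3995 ± 61.2 to 169 ± 15.5 (SD, n = 3).

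Parental means of the 14 genes ranked highest were at most 39.7 (LAMP5), so the order among them depends on the pseudocount. The other genes with the largest rise were LHFPL6 (log2 change 5.76), TANC1 (5.17), GLUL (4.49), XIRP2 (4.47), LAMP5 (4.47), CLEC2B (4.46), FBXO16 (4.31), SGMS2 (4.28), PDE3A (4.20) and PCDH10 (4.13). GLUL encodes glutamine synthetase, SGMS2 a sphingomyelin synthase and PDE3A a cyclic nucleotide phosphodiesterase. Those with the largest fall included the cancer-testis antigen genes MAGEA6 (−4.15) and MAGEA12 (−3.57), whose near-identical relatives can bind the same probes, so that either value is uncertain. ST3GAL6 (−4.03), PXDNL (−3.84), ADGRL2 (−3.59), RBPMS2 (−3.48), CLECL1 (−3.38), CLNK (−3.06) and PKIB (−2.99) fell as well. EPAS1, which encodes the hypoxia-inducible factor HIF-2alpha, fell from 1462 ± 62.7 to 148 ± 5.06 (SD, n = 3). AHR, the aryl hydrocarbon receptor, fell from 968 ± 52.1 to 98.1 ± 7.04 (SD, n = 3), and P4HA2, a prolyl hydroxylase that acts on collagen, from 625 ± 21.6 to 62.4 ± 4.57. The rule took only genes whose mutated values lay on one side of every parental value. Adjusted p with limma and Benjamini-Hochberg adjustment was at most 9.1e-07 for the 14 that rose and at most 4.9e-06 for the 14 that fell. Other probe sets of TANC1 (0.14) and FABP4 (−0.02) did not show the rise, and with a pseudocount of 1 TANC1 did not pass (0.19). Those of GLUL ran from −1.03 to 1.70, and those of PCDH10 from −0.17 to 2.75. Among the falls, other ST3GAL6 probe sets ran from −2.86 to −0.33 and those of CLNK from −2.44 to −1.33, and that of P4HA2 gave −0.76. Of 64 named genes other than CXCR4 with another tested probe set, 37 had one of opposite sign or over 1.5 times smaller, and 14 one of opposite sign.

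**Figure D2:**
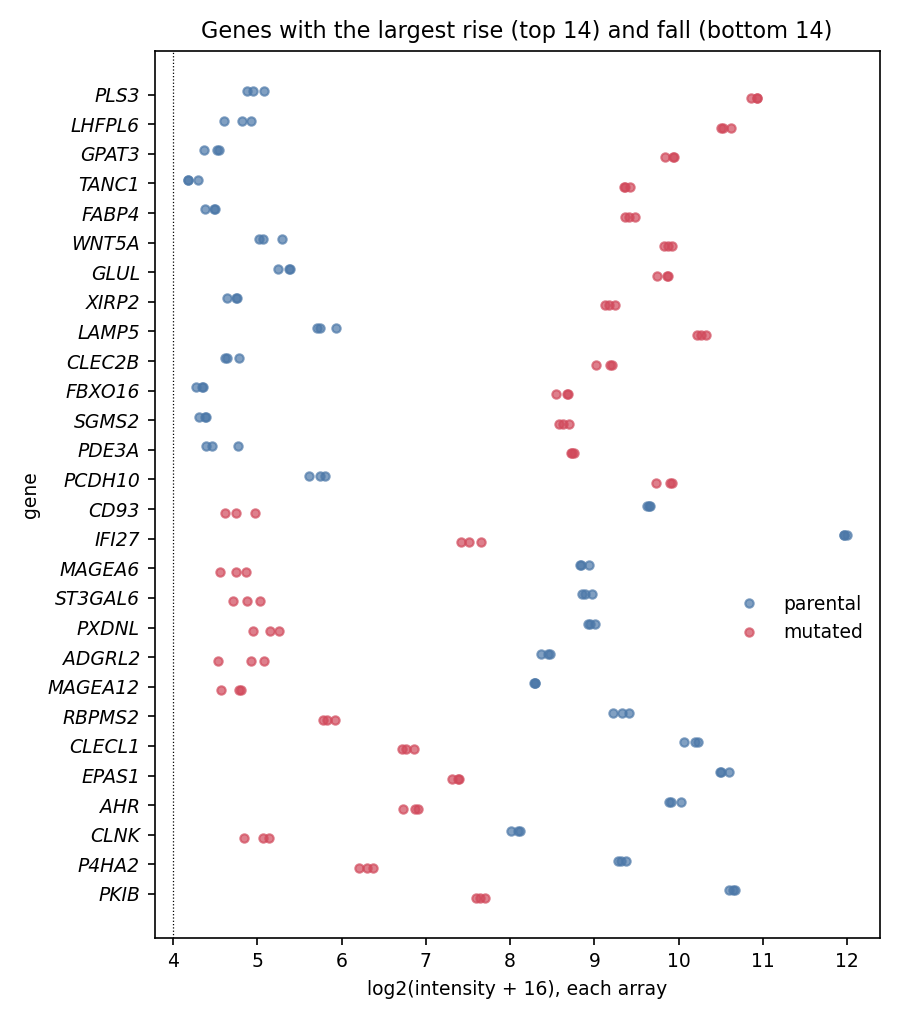
Log2(intensity + 16) on each array (x axis) for the 14 genes with the largest rise and the 14 with the largest fall (y axis). Points are arrays, blue for parental and red for mutated cells, and the dotted line marks an intensity of 0. Genes were chosen so that the groups do not overlap, and they run from the largest rise, PLS3 (5.94), through CD93 (−4.87) to PKIB (−2.99).

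Of 13644 genes tested, 4109 rose and 2574 fell in mutated cells at an adjusted p under 0.05 (limma with Benjamini-Hochberg adjustment), together 49.0%. Most of these changes were small: 515 genes rose and 212 fell by at least 2-fold, and 154 rose and 55 fell by at least 4-fold. Of the 515 genes, 201 had a parental mean under the highest array median of 31.83, and of the 212 genes, 59 had a mutated mean under it. The groups did not overlap in 8346 genes (61.2%), where chance gives 10%. Of the 727 genes changed at least 2-fold, 360 had another tested probe set, which agreed in sign on every probe set in 313 and also reached 2-fold in 204. Over all tested probe sets 10120 rose and 5433 fell. The share of calls that were higher was 65.1% of probe sets and 61.5% of genes, against 49.97% and 49.4% with quantile normalization and 50.7% and 46.1% with median centring. The balance of rises and falls differed between these scalings.

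**Figure D3:**
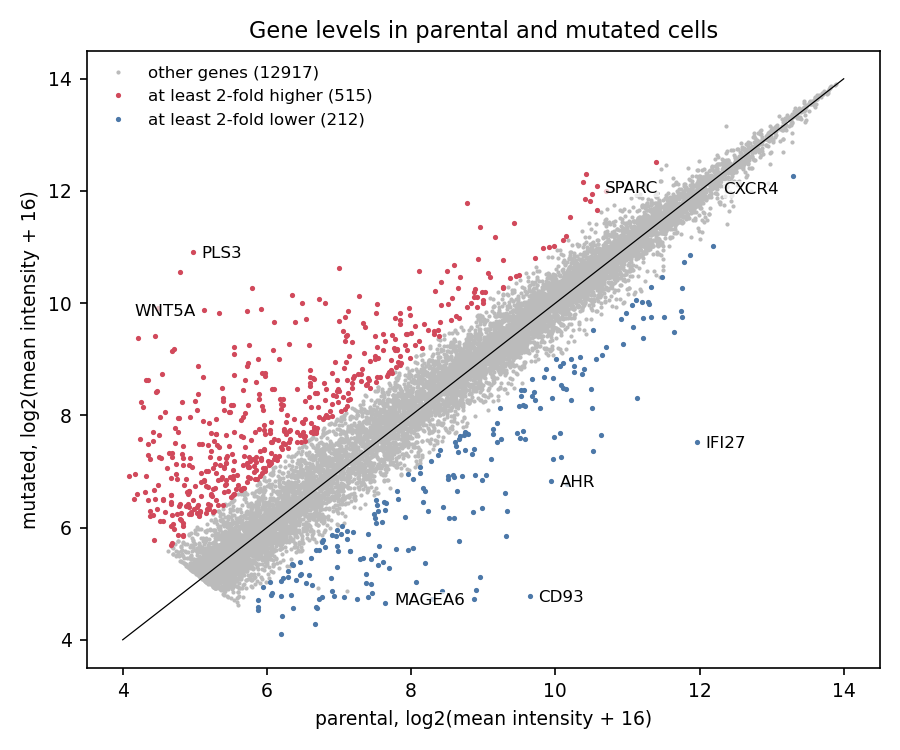
Each point is 1 of 13644 genes, placed by the log2(mean intensity + 16) of parental (x axis) and mutated cells (y axis). Red marks the 515 genes at least 2-fold higher and blue the 212 at least 2-fold lower in mutated cells, grey the rest, and the line equal levels.

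Genes induced by interferon were mostly lower in mutated cells: of 38 tested, 21 fell, 5 rose and 12 did not pass (22 and 5 adjusted over the list alone). Besides IFI27, OAS3 fell from 2516 ± 123 to 993 ± 18.9, HERC6 from 390 ± 10.3 to 175 ± 9.62, and DDX60 from 2405 ± 29.2 to 1336 ± 7.78 (SD, n = 3). The other OAS3 probe set gave −0.45. The 5 that rose were IFI6 (0.47), IFIT3 (0.35), LY6E (0.24), RIGI (0.23) and BST2 (0.20). Target genes of NF-kB, the transcription factor of inflammatory signalling, fell in 17 of 28, rose in 3 and did not pass in 8 (17 and 3 adjusted over the list alone). CD83, an activation marker, fell from 2847 ± 38.5 to 1397 ± 37.8, the chemokine gene CCL22 from 10032 ± 340 to 4940 ± 131, and the adhesion receptor gene CD44 from 2862 ± 154 to 1600 ± 46.0 (SD, n = 3). Other probe sets of CD44 ran from −0.60 to 0.22. IL10, which encodes an anti-inflammatory cytokine, rose from 46.0 ± 8.47 to 211 ± 21.95 (SD, n = 3), and CCL5 (0.65) and SOD2 (0.59) rose as well. Of 16 genes of MHC class II presentation, 8 fell, 2 rose and 6 did not pass (8 and 2 adjusted over the list alone). HLA-DMB fell from 2362 ± 48.2 to 649 ± 22.2 and HLA-DMA from 2637 ± 68.2 to 1505 ± 48.8, both parts of the complex that loads peptides (SD, n = 3). The costimulatory genes CD86 (−0.73) and CD80 (−0.82) fell, while LGMN (0.72) and CTSS (0.30), which encode lysosomal proteases, rose. CD80 has probe sets that differ, and without any 1 parental replicate another one represented it, with a log2 change of −0.14 to −0.08 that did not pass.

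MYC target genes fell in 18 of 33, rose in 1 (FBL, 0.22) and did not pass in 14 (18 and 1 adjusted over the list alone). TFRC, the transferrin receptor, fell from 7893 ± 17.0 to 4528 ± 73.5, and the ribosome biogenesis genes RRS1 (−0.63) and UTP20 (−0.55) and the RNA polymerase I gene POLR1B (−0.43) fell with it. Other probe sets of TFRC ran from −0.98 to 0.077. Of 39 genes of the G1/S transition, 17 fell, 7 rose and 15 did not pass (17 and 8 adjusted over the list alone). UHRF1 (−0.46), RRM2 (−0.42) and POLA1 (−0.39), which serve DNA synthesis and the upkeep of DNA methylation, fell, and CCND1, cyclin D1, rose from 82.0 ± 12.8 to 216 ± 10.6 (SD, n = 3). Proteasome subunit genes fell in 10 of 28, rose in 0 and did not pass in 18 (10 and 0 adjusted over the list alone), among them PSMD12 (−0.53), PSMD11 (−0.44), PSMC4 (−0.41) and PSMD6 (−0.34). Another probe set of PSMD11 gave 0.11 when those with the suffixes _s_at and _x_at were left out, and PSMD6 did not pass as the mean of its probe sets (−0.066).

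Genes of glycolysis and the hypoxia response rose in 20 of 35, fell in 1 (P4HA2) and did not pass in 14 (20 and 1 adjusted over the list alone). MXI1, a MYC antagonist, rose from 392 ± 6.32 to 1406 ± 44.4, the glycolysis regulator PFKFB4 from 457 ± 19.1 to 1208 ± 21.9, and BNIP3L, a gene of mitophagy, from 2375 ± 76.7 to 4415 ± 39.0 (SD, n = 3). Of 22 p53 target genes, 11 rose, 0 fell and 11 did not pass (13 and 0 adjusted over the list alone). SESN1 rose from 83.9 ± 6.81 to 180 ± 8.60, TP53INP1 from 481 ± 31.9 to 869 ± 18.4 and the growth arrest gene GADD45A from 2489 ± 26.0 to 3386 ± 53.3, and PLK2 from a dim 14.1 ± 6.20 to 84.6 ± 10.4 (SD, n = 3).

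These 8 of 40 lists passed camera with the preset correlation. The adjusted p (limma's camera with Benjamini-Hochberg adjustment) was 9.5e-05 for interferon response (median log2 change −0.25), for MYC targets (−0.20) and for glycolysis and hypoxia (0.28). It was 3.1e-04 for NF-kB targets (−0.27), 0.0057 for MHC class II presentation (−0.18) and for proteasome subunits (−0.09), 0.019 for p53 targets (0.20) and 0.020 for G1/S genes (−0.11). None of these calls held with a correlation estimated from the data: camera gave adjusted p = 0.64 with an estimated correlation for 7 of them and 0.68 for proteasome subunits, and 1 of the 40 lists had an unadjusted p under 0.05. That list was p53 targets, with an estimated correlation of −0.0095, under the preset 0.01. Its unadjusted camera p still rose from 0.0033 to 0.032, so a higher correlation does not explain the loss in that list. With an estimated correlation, camera tests on only the degrees of freedom that the 6 samples leave, which lowers its power. The lost calls therefore do not tell correlated genes from low power. In p53 targets the call was also lost with the dimmest 60% left out (camera, adjusted p = 0.056) and without probe sets of the suffixes _s_at and _x_at (0.087), as it was in proteasome subunits (0.22). Some medians moved by over 1.5 times. Without parental replicate 1, 2 or 3 that of MHC class II presentation was −0.096, −0.072 and −0.11 (camera, adjusted p from 0.014 to 0.035). These are the settings in which another probe set represented its member CD80. Without mutated replicate 1, 2 or 3 the median was −0.17, −0.19 and −0.18. With median centring the medians of G1/S genes, proteasome subunits and p53 targets were −0.19, −0.17 and 0.12. Without the suffixes _s_at and _x_at, glycolysis and hypoxia gave 0.68, p53 targets 0.36 and proteasome subunits −0.026. As the mean of a gene's probe sets, interferon response gave −0.16 and p53 targets 0.32. Other groupings of the 6 samples gave up to 7 lists, but part of the group difference remains in them, so this is no rate of false calls.

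**Figure D4:**
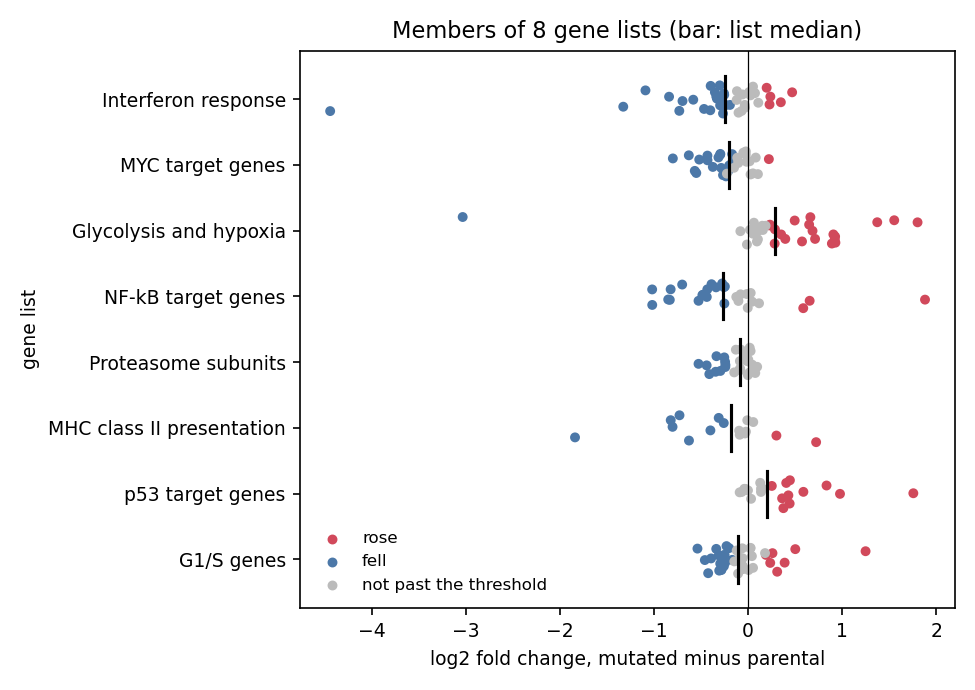
Log2 fold change, mutated minus parental (x axis), of the tested members of the 8 gene lists past camera (y axis). Each point is a gene, red where it rose, blue where it fell and grey where it did not pass, spread vertically for legibility, and black bars are list medians, from −0.27 for NF-kB targets to 0.28 for glycolysis and hypoxia. No median turned sign with quantile normalization or median centring.

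The other 32 lists did not pass camera, and the median of 12 of them turned sign with quantile normalization or median centring, so counts of members are given here in place of list directions. Such counts depend on the scaling as well: 61.5% of gene calls were higher here, against 49.4% with quantile normalization and 46.1% with median centring. They are to be read beside the 4109 genes that rose and the 2574 that fell among all 13644 tested. Components of CXCR4 signalling rose in 9, fell in 10 and did not pass in 13 of 32 (10 and 10 adjusted over the list alone). STAT3 fell from 1956 ± 42.7 to 1010 ± 39.9, and PXN, the focal adhesion protein paxillin, from 104 ± 20.5 to 13.3 ± 2.96 (SD, n = 3). Chemokine and sphingosine phosphate receptor genes rose in 7 and fell in 7 of 18 (7 and 7 adjusted over the list alone). CXCR5, a receptor that guides B cells to follicles, fell from 183 ± 12.9 to 9.27 ± 1.85, and CCR9, a gut-homing receptor, from 459 ± 13.2 to 107 ± 4.59 (SD, n = 3). Adhesion and integrin genes rose in 14 and fell in 9 of 32 (14 and 9 adjusted over the list alone), with JAM2 rising from 34.9 ± 3.29 to 333 ± 18.8 and ITGAM from 167 ± 8.80 to 890 ± 29.6 (SD, n = 3). The other JAM2 probe set gave 0.90. For ITGAM, another probe set gave −0.18 without those of the suffixes _s_at and _x_at. Genes of migration and the cytoskeleton rose in 11 and fell in 7 of 38 (11 and 7 adjusted over the list alone), DOCK8 falling by 1.67 and ACTN1 rising by 0.61 on the log2 scale, though not on its other probe sets (−0.035 and 0.0055). Matrix protease and invasion genes rose in 6 and fell in 8 of 19 (7 and 8 adjusted over the list alone), with HPSE, heparanase, rising by 2.42 and SPARC by 1.51.

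Genes of B cell identity rose in 8 and fell in 7 of 22 (8 and 7 adjusted over the list alone), with CR2 (1.02) and FCRLA (1.02) rising. B cell receptor signalling genes rose in 4 and fell in 9 of 25 (6 and 9 adjusted over the list alone). The kinase gene BLK fell from 1335 ± 61.4 to 439 ± 5.05 and the inhibitory Fc receptor gene FCGR2B rose from 1120 ± 9.31 to 2347 ± 88.0 (SD, n = 3). CD79B (0.63), CD72 (0.41) and CD79A (0.23) rose too. Plasma cell markers rose in 4 and fell in 9 of 22 (4 and 9 adjusted over the list alone). TNFRSF17, the receptor BCMA, fell from 3417 ± 91.3 to 911 ± 40.1, while CAV1 rose from 306 ± 13.3 to 1174 ± 25.3 (SD, n = 3), with MZB1 (0.48), PRDX4 (0.24) and SEL1L (0.23). Germinal centre markers rose in 2 (STAP1, 0.92, and S1PR2, 0.18) and fell in 5 of 11 (2 and 5 adjusted over the list alone), the 5 being LMO2 (−1.03), IRAG2 (−1.001), ELL3 (−0.66), CD38 (−0.65) and MYO1E (−0.42). MHC class I presentation genes rose in 2 (PDIA3, 0.43, and ERAP2, 0.21) and fell in 2 (TAP2, −0.65, and NLRC5, −0.21) of 18 (1 and 2 adjusted over the list alone).

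Notch and Wnt pathway genes rose in 11 and fell in 5 of 22 (11 and 5 adjusted over the list alone). ROR1, a receptor of WNT5A, rose from 9.64 ± 0.338 to 137 ± 0.906 (SD, n = 3), with 0.78 and 1.46 on its other probe sets, and the 5 that fell were DTX1 (−2.63), NOTCH2 (−1.08), NOTCH1 (−0.89), NRARP (−0.74) and JAG2 (−0.69). FOXO target genes rose in 10 and fell in 3 of 17 (10 and 4 adjusted over the list alone). IL7R, the receptor of interleukin 7, rose from 16.8 ± 2.15 to 258 ± 9.15 (SD, n = 3) and FBXO32 by 1.42 on the log2 scale (0.27 on its other probe set), while KLF2 (−1.67), S1PR1 (−0.999) and SESN3 (−0.18) fell. Immediate early genes rose in 4 and fell in 8 of 16 (4 and 8 adjusted over the list alone), with EGR3 falling by 0.64 and NR4A2 (0.76), DUSP1 (0.57), ATF3 (0.48) and KLF6 (0.29) rising. Genes of ERK pathway output rose in 6 and fell in 7 of 19 (8 and 7 adjusted over the list alone). DUSP4, an ERK phosphatase, fell from 3200 ± 79.8 to 700 ± 25.4 and SPRED1 rose from 41.7 ± 1.46 to 137 ± 1.75 (SD, n = 3). PI3K, AKT and mTOR pathway genes rose in 8 and fell in 6 of 25 (8 and 8 adjusted over the list alone), with PHLPP1, an AKT phosphatase, rising by 1.53. Cytokine and growth factor genes rose in 12 and fell in 13 of 33 (12 and 13 adjusted over the list alone). PDGFA fell from 712 ± 17.4 to 179 ± 6.30 and IL18 rose from 5.84 ± 1.45 to 75.3 ± 1.71 (SD, n = 3).

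G2/M genes rose in 18 and fell in 2 (TPX2, −0.21, and CENPA, −0.18) of 40 (18 and 3 adjusted over the list alone), with BIRC5 (0.51) and CDC25C (0.39) rising. CDK inhibitors and tumour suppressors rose in 6 and fell in 4 of 23 (6 and 4 adjusted over the list alone). PRDM1, which encodes the plasma cell factor BLIMP1, fell from 349 ± 16.4 to 105 ± 3.32 and CDKN2A rose from 94.2 ± 3.91 to 190 ± 11.2 (SD, n = 3), while TNFAIP3 (−0.53), CYLD (−0.52) and RBL1 (−0.50) fell. Anti-apoptotic genes rose in 4 and fell in 6 of 16 (4 and 6 adjusted over the list alone), with PIM2 (−0.60) and CFLAR (−0.55) falling and BIRC5, BCL2L2 (0.35), PIM1 (0.34) and BAG1 (0.17) rising. Other probe sets of CFLAR ran from −0.79 to 0.060. Pro-apoptotic genes rose in 6 and fell in 3 of 23 (5 and 3 adjusted over the list alone), with BAD (0.40) rising and BMF (−0.60), DAPK1 (−0.38) and CYCS (−0.22) falling. Other probe sets of BAD ran from −0.11 to 0.18. Oxidative phosphorylation genes rose in 8 and fell in 0 of 39 (5 and 0 adjusted over the list alone), SDHD by 0.32 and NDUFC1 by 0.30. Cholesterol synthesis genes rose in 3 (DHCR7, 0.37, EBP, 0.36, and STARD4, 0.20) and fell in 10 of 18 (3 and 10 adjusted over the list alone). LSS (−0.38) was among those that fell, though not as the mean of its probe sets (−0.10). Amino acid stress genes rose in 6 and fell in 13 of 27 (7 and 14 adjusted over the list alone), with STC2 (0.95) rising and WARS1 (−0.75) falling. Heat shock and oxidative stress genes rose in 6 and fell in 9 of 23 (6 and 9 adjusted over the list alone), with HSPA6 (0.64) rising and GCLM (−1.15) falling. Unfolded protein response genes rose in 7 and fell in 6 of 24 (7 and 6 adjusted over the list alone), with SEC24D (0.67) and ATF6 (0.50) rising. For ATF6, its other probe sets ran from −0.29 to 0.39. Cytosolic ribosomal protein genes rose in 2 (RPS9, 0.17, and RPS12, 0.15) and fell in 0 of 36 (0 and 0 adjusted over the list alone), and neither call held with median centring. Histone modifier genes rose in 12 and fell in 6 of 36 (13 and 7 adjusted over the list alone), KDM5B by 0.65, which did not pass without the suffixes _s_at and _x_at (0.034). HDAC9 rose by 1.17 from a dim 19.9 ± 0.462 (SD, n = 3), but other settings chose another probe set that fell (−1.53 with quantile normalization).

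Markers of other cell types rose and fell within the same lists, apart from erythroid and platelet markers. Markers of T and NK cells rose in 4 and fell in 2 of 13 (4 and 2 adjusted over the list alone), with BCL11B rising from 12.3 ± 2.45 to 286 ± 37.4 (SD, n = 3), TRAT1 (1.81), LAT (0.29) and CD28 (0.20) rising, and LCK (−0.92) and PRF1 (−0.58) falling. Myeloid markers rose in 3 and fell in 2 of 12 (2 and 1 adjusted over the list alone). S100A9 rose from 674 ± 26.7 to 2734 ± 64.4 (SD, n = 3), with ITGAM and FCER1G (0.21) rising and CEBPE (−0.44) and VCAN (−0.42) falling. Stromal and endothelial markers rose in 4 and fell in 2 of 10 (4 and 2 adjusted over the list alone). SPARC rose from 1509 ± 50.2 to 4314 ± 213 (SD, n = 3), FN1 by 1.44, PECAM1 by 0.72 and ENG by 0.56, while ACTA2 (−0.70) and COL1A1 (−0.67) fell. Erythroid and platelet markers rose in 0 and fell in 0 of 7 with limma (0 and 0 adjusted over the list alone). Epithelial markers and markers of a kidney-derived packaging line rose in 1 (LIN28B, 2.13) and fell in 2 (ELF3, −0.59, and CLDN7, −0.19) of 6 (1 and 2 adjusted over the list alone), and ELF3 did not pass without the suffixes _s_at and _x_at (−0.10). In 4 lists the median and the mean differed in sign: CXCR4 signalling, myeloid markers, pro-apoptotic genes and epithelial markers. The mean and camera's direction differed in 9 lists: cytokines, migration, unfolded protein response, PI3K pathway, CDK inhibitors, B cell identity, myeloid, pro-apoptotic and epithelial. In all 9 the mean was above 0 and camera's direction was down. Camera compares a list with the other tested genes, and the median log2 change over all genes was 0.038. Its direction therefore does not mean that the genes of a list fell.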

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

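The alternatives were planned, except that the 2 other CXCR4 probe sets were run under each alternative after the results were seen. The counts of changed probe sets and genes stayed within 1.5 times those reported, apart from the following, whose cause follows from the setting. With a pseudocount of 64, which shrinks the change of dim genes, 448 genes changed at least 2-fold (314 higher and 134 lower). Without probe sets of the suffixes _s_at and _x_at, 10137 probe sets changed and 3185 were lower, as fewer were tested. With an estimated correlation camera called 0 lists (1 at an unadjusted p under 0.05), and fry, which does not compare a list with other genes, called 31. Among the lists that fry called, its direction was opposite to camera's for the PI3K, AKT and mTOR pathway (median 0.030), B cell identity (0.042) and myeloid markers (−0.090). It was also opposite, with no call by either test, for matrix proteases and invasion, pro-apoptotic genes and the unfolded protein response.

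On its brightest probe set CXCR4 kept its size without the filter (−0.15, adjusted p = 0.068 with limma) and with the replicate number as a block (−0.15, adjusted p = 0.070), and lost the threshold. The loss therefore lies in the error or the adjustment and not in the estimate. Without the filter p was adjusted over 54613 probe sets in place of 32768, and the block terms take up degrees of freedom. CXCR4 was −0.23 with median centring and −0.41 as the mean of the 3 probe sets. Over its other alternatives that kept all samples adjusted p was 9.2e-04 to 0.038. The other CXCR4 probe sets passed in 15 of 15 alternatives each, with log2 changes of −0.57 to −0.44 for _x_at and −0.65 to −0.52 for _s_at.

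Leaving out each sample in turn gave 13064 to 15295 changed probe sets (8502 to 9928 higher, 4314 to 5367 lower), 5587 to 6483 genes (3450 to 3922 higher, 2025 to 2561 lower), 720 to 743 genes at least 2-fold (504 to 536 higher, 202 to 225 lower), 8 to 10 lists, and −0.17 to −0.15 for CXCR4 on its brightest probe set. HDAC9 turned from 1.17 to −1.53 with quantile normalization, to −0.24 as the mean of its probe sets, and to −1.41, −1.48 and −1.40 without mutated replicate 1, 2 and 3 (−1.48 to 1.18 over the 6 samples left out in turn). GLUL (−1.03), PSMD11 (0.11) and ITGAM (−0.18) turned without the suffixes _s_at and _x_at. Apart from the mean of the probe sets of HDAC9, which averages over probe sets that differ in sign, these turns follow a change of probe set. Of 1945 values of 116 named genes under alternatives, 1913 kept direction and side of the threshold, 24 lost it, in 8 genes (RPS9, RPS12, TANC1, PSMD6, LSS, ELF3, KDM5B and CD80), and 8 turned. Among the 28 genes of largest change, 468 of 471 values were kept, the exceptions being TANC1 and GLUL.

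The replicate number as a block gave 14897 probe sets, 6258 genes and 726 genes at least 2-fold, and ended the calls of CXCR4 on that probe set and RPS12 among named genes and lists. Deviations of samples with the same number correlated at 0.11, 0.027 and 0.11, so the numbers were not taken to pair the samples, although each sample correlated best with its own number, a hint from the data only. Low signal limits dim genes: values near 1 have no detection call, and folds against them depend on the pseudocount (953 genes at least 2-fold with a pseudocount of 1, within 1.5 times the 727 reported).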

Other observations

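The tests of array scaling on the 2-fold genes, collagen-making cells, strongly changed genes in windows, windows after quantile normalization, windows without the gene counted in them and the cancer-testis list were chosen after the results were seen. The interferon response list without IFI27 was added after the data were seen, with its prediction written before its result. The other tests were written before.

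Immunoglobulin genes were bright in both groups and differed little. Of 18 immunoglobulin probe sets above an intensity of 1000, 15 were lower in mutated cells, and the highest fold was 1.72. IGHM, the mu heavy chain, read 9118 ± 324 in parental and 6629 ± 267 in mutated cells, and IGLC1, a lambda light chain, 9950 ± 328 and 7511 ± 44.3 (SD, n = 3). A 4-fold difference, the limit set for another B cell line under one of the labels, was not reached. This argues against a line that makes another heavy or light chain. A line with the same mu and lambda chains could be missed, and a subclone of BCWM1 is not argued against.

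Cancer-testis antigen genes were dim apart from MAGEA6 and MAGEA12. Of 9 tested, 5 fell with limma and 0 rose. Besides that pair, MAGEA1 went from 57.4 ± 11.4 to 1.12 ± 0.202, CTAG2 from 49.6 ± 4.45 to 23.3 ± 2.62 and PRAME from 58.3 ± 14.2 to 30.4 ± 5.85 (SD, n = 3). The probe sets of MAGEA1 and CTAG2 carry the suffix _x_at, so relatives may share their signal and the falls may not be separate. Mutated MAGEA1 values were near 1, where no detection call was used. Camera without MAGEA6 and MAGEA12 gave an adjusted p of 0.063, so a shift of the list as a whole did not pass. Without IFI27, the interferon response list still passed camera (adjusted p = 1.9e-04, median log2 change −0.24), so that gene alone did not carry it. With IFI27, the list had adjusted p = 0.64 with an estimated correlation in camera, a setting that also has less power. Its camera call thus depended on the setting, and the loss does not tell correlated genes from low power.

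As many as 727 genes differed at least 2-fold. Array scaling is argued against, since 705 genes did with quantile normalization and 714 with median centring. Neighbouring genes shifted together: 132 windows of 21 neighbours had a median beyond 0.3 (129 higher, 3 lower), against at most 62 in 100 random gene orders. Without the 2-fold genes there were 40, against at most 29. With quantile normalization there were 151, against at most 40 in random orders. These split into 78 higher and 73 lower, so the balance of directions depended on the scaling. A gain or loss of chromosomal regions may account for such stretches, the longest from STAU2 to OTUD6B-AS1 with 33 of 50 genes called higher, but 10.2% of the 2-fold genes lay in windows shifted their way, a share raised by their own part in the median (4.97% with each gene left out of its windows, against 2.12% of all placed genes), and too few to account for most of them. Stromal cells cannot be told apart by the planned test. The median of 5 genes was at 39.99% of the level of the 14 most risen genes. That median was FN1, which rose from 105 ± 16.2 to 312 ± 30.2 (SD, n = 3). Of the collagen genes, 3 of 3 were dim or not higher in mutated cells (COL1A2 14.8 ± 2.49, COL3A1 4.58 ± 2.78, COL1A1 442 ± 42.9, SD, n = 3). COL1A1 was at 56.6% of the level of the 14 genes and counted only as not higher. These values show no collagen mRNA that was both bright and raised. The rule was written after the results were seen, so it is no independent test against collagen-making cells. The mutation, a subclone, a line with the same immunoglobulin chains and the way the cells were made stay open, as untested.

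CXCR4 was lower on 3 probe sets, by unequal amounts. Array scaling is argued against, since the _s_at probe set stayed lower with quantile normalization (−0.58, adjusted p = 0.0013 with limma) and median centring (−0.65, 9.1e-04). The brightest probe set fell less, by 0.38 (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 allows). Compression of bright signals may account for this and cannot be told apart. In 96 other genes the median ratio of bright to dim change was 0.429. Its 95% bootstrap interval, over genes, was 0.335 to 0.503 and spans the limit set. The dim probe sets were chosen for passing the threshold with a clear change, and the most changed was taken where several did. That choice lowers the ratio even without compression, so the test cannot decide. The ratio in CXCR4 was 0.29, and 32 of the 96 genes had one as low. In CXCR4 it was taken against the mean of its other 2 probe sets, so the ratios are not fully alike. An introduced copy read by some probe sets was not tested.

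The glycolysis and hypoxia list rose at camera's preset correlation. Its HIF targets that are not glycolytic had a median log2 change of 0.89, with 11 of 13 rising and 1, P4HA2, falling. The 95% bootstrap interval of that median, 0.495 to 0.924, resamples the 13 genes and not the arrays. It therefore does not measure the spread between samples. The median was 0.88 with quantile normalization and 0.81 with median centring, and 21 glycolytic genes had a median of 0.157, with 9 rising and 0 falling. Lower oxygen in the mutated cultures, for example through denser growth, is consistent with these values, as is HIF activity at unchanged oxygen, which was not tested. EPAS1 fell, and neither oxygen nor cell density is given in the sources used here. The list's call was lost with an estimated correlation, a setting in which camera also has less power.

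The 6 samples can be split in 10 ways, too few for a share under 0.05. The real split gave 15553 probe sets, 6683 genes and 727 genes at least 2-fold, the highest other split 0 of each, so 1 split gave counts as large. It gave 8 lists, and the highest other split 7. Every other split mixes parental and mutated samples on both sides, so the group difference adds to the spread within each side. The counts of 0 in those splits follow from this and do not measure chance. The mix is unequal, so part of the group difference also stays between the sides. The list counts of those splits therefore do not measure chance either.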
